A study of Homo sapiens with 8 samples.

How the data were processed

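RNA-seq was run on 8 libraries of the human cell line THP-1, 4 in each of 2 groups (LPS, and LPS with 3-HPA). The labels' protocols record differentiation with PMA, total RNA extracted with TRIzol and libraries made with a VAHTS Universal V6 kit. Whether poly(A) RNA was selected or ribosomal RNA removed, whether the libraries were stranded, the read length and the annotation release are not given in the sources used here. Per the submitters' processing notes, reads were handled with fastp 0.22.0, HISAT2 2.1.0 and featureCounts (no version given) on GRCh38. The deposited values are FPKM (fragments per kilobase of gene, scaled by the library total), per the labels, in 1 table of 30233 Ensembl genes by 8 libraries. Genes at 0 in every library are not in it.

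Depth was recovered from the FPKM values, since each is a whole number of reads divided by gene length and library total. Library totals and gene lengths that made the values whole (within 0.01) were searched for, and this gave 35647756 to 41859879 reads per library, of which 99.88 to 99.89% fall on genes in the table. Recovered lengths equalled the union of exons in GENCODE 29 for 13211 of 28364 genes compared. In each library more genes held 2 reads (1885 to 2014) than 1 read (1142 to 1240), so mates of a pair were apparently counted separately. At this depth 1 read in a gene of 2 kb corresponds to at most 0.014 FPKM, and intervals and tests cover neither PCR duplicates nor errors of alignment. On simulated tables of 5696 genes the 8 totals came back exactly and all reads of a gene came back for 93.0% of genes (96.0% of those with 100 reads or more).

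Symbols came from the reference's table of gene names, which matched 30221 identifiers and left 12 without a name. Positions are on GRCh38 from GENCODE 29, which gives one for 28364 genes. Genes with near-identical copies, such as ribosomal protein, metallothionein, histone and HLA genes, are uncertain, as are overlapping and antisense genes.

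The choices in this paragraph were fixed before the data were examined. Groups were compared with limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), in genes with an FPKM of at least 0.5 in at least 4 libraries, with a mean-variance trend, two-sided tests and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. The fold change is LPS with 3-HPA minus LPS. No scaling was added to that of the deposited values. Gene lists, 39 in number, cover metabolism, inflammation, interferon response, stress, lipids, growth, macrophage identity and other cell types. Those with at least 5 tested genes were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The genes named were the 12 with the largest change in each direction among genes with an adjusted p under 0.05, a symbol, a mean of at least 1 FPKM and groups that do not overlap; up to 4 genes with the smallest p from each list; and GAPDH, HK2, PFKFB3, LDHA, PKM, SLC2A1, HIF1A, PDK1, PDK4, TNF, IL1B, IL6, CXCL8, CXCL10, IL10, NLRP3, ACOD1, PTGS2, MRC1, HIBCH, HIBADH and ALDH6A1. Loci without a proper name were passed over. Of these, IL10 (2 to 12 reads per library) lay below the filter and MRC1 was not analysed here; a few others that the rule selects are not used here. Genes named outside the rule are said to have been chosen after their values were seen.

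The alternatives fixed in the same way were pseudocounts of 0.1 and 0.5, no filter, a filter at 1 FPKM, equal FPKM totals, TMM scaling, quantile normalisation, limma without trend, library weights, the replicate number as a block, leaving out each library, and treat against a 1.2-fold change. Added after seeing the data were limma voom on the recovered reads and equal FPKM totals outside the mitochondrial genome. The plan allowed for a table of counts, but the table held FPKM, so the test planned for FPKM was used. TMM factors were written out by hand from their definition. The limma step was tested on simulated data for this comparison with 50 genes planted at each of 4 fold sizes among 12559 tested: it recovered 38 at 1.25-fold, 44 at 1.5-fold, 49 at 2-fold and 49 at 3-fold, and called 9 unplanted genes. Rises and falls were planted in equal number, and far fewer genes changed than the 43.7% called in the real data. These rates therefore need not carry over. Computation also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No library was left out. The raw reads were not used here.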

Results

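Gene expression was measured by RNA-seq in 8 libraries of THP-1 macrophages, 4 given LPS alone and 4 given LPS together with 3-HPA. THP-1 is a human monocytic leukaemia line, turned here into macrophage-like cells with PMA at 100 ng/ml for 24 h and then kept without PMA for 24 h. LPS, a bacterial outer-membrane component that activates inflammatory genes, was used at 100 ng/mL. 3-HPA (3-hydroxypropionic acid, a small organic acid) was used at 5 mM and, per the labels' treatment protocol, was added at the same time as LPS, whereas the series description speaks of pretreatment. The length of the LPS exposure is not given in the sources used here. Depth, recovered from the FPKM values, was 37509810, 41270419, 38475879 and 41859879 reads in LPS libraries 1 to 4 and 37573399, 40362671, 35647756 and 37294695 reads in 3-HPA libraries 1 to 4. Between 22917 and 23621 genes lay above 0 in each library. Pearson correlations across genes, which are not independent replicates, ran from 0.992 to 0.993 within groups and from 0.981 to 0.982 between them, and the first principal component, with 53.7% of the variance, separated the groups. No library was unstimulated or given 3-HPA alone, so every difference lies between LPS-stimulated states. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

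The comparison addresses what 3-HPA does to LPS-stimulated macrophages, a question that the series title frames around glycolysis, mitochondrial oxidation and the glycolytic enzyme GAPDH. With 3-HPA, genes for neutrophil-attracting CXC chemokines (CXCL1, CXCL3), the alarmin subunit S100A9 and secreted matrix metalloproteinases (MMP1, MMP10) rose. Interferon-stimulated genes fell, among them CXCL11 for a T-cell chemokine and the antiviral genes IFIT1 and IFIT2, together with CCR7, which encodes a receptor for migration to lymph nodes. S100A9 (ENSG00000163220; GRCh38 chromosome 1, 153357854 to 153361027) went from 1.48 ± 0.208 to 18.4 ± 0.854 FPKM (mean ± SD, n = 4 per group), a log2 fold change of 2.97 (SE 0.061, limma adjusted p = 6.56e-09). CXCL3 (ENSG00000163734; chromosome 4, 74036589 to 74038807) went from 70.4 ± 1.53 to 201.5 ± 4.92 FPKM, with a log2 fold change of 1.504 (SE 0.022, adjusted p = 2.21e-09). Other large increases were in SLC16A6 (a monocarboxylate transporter family member, 2.08), STC1 (a secreted glycoprotein hormone, 1.90), THBD (the anticoagulant receptor thrombomodulin, 1.72), TMEM119 (a membrane protein used as a microglial marker, 1.67), IL1R2 (a decoy receptor for IL-1, 1.65), CLEC5A (a myeloid lectin receptor, 1.63), MMP10 (1.52), MMP1 (1.495) and CXCL1 (1.49). On the log2(FPKM + 1) scale the decreases were led by MNDA, a nuclear protein of myeloid cells (ENSG00000163563; chromosome 1, 158831317 to 158849506), which fell by 2.13 (SE 0.054, adjusted p = 1.43e-08). It was followed by CXCL11 (-2.10), IFIT1 (-1.81), the nucleotidase NT5C3A (-1.78), the cytidine deaminase APOBEC3A (-1.73), CCR7 (-1.67), IFIT2 (-1.60), the adaptors PLEKHA4 (-1.56), HSH2D (-1.51) and STAP1 (-1.47), the ISG15 protease USP18 (-1.46) and the ubiquitin ligase NEURL3 (-1.39). By the ratio of mean FPKM, APOBEC3A (5.71-fold) fell further than MNDA (5.08-fold).

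Of 12499 genes tested, 5462 (43.7%) passed an adjusted p of 0.05, with 1967 higher and 3495 lower with 3-HPA. Most changes were small: 4631 of them (84.8%) had an absolute log2 fold change under 0.5, and 100 genes changed at least 2-fold, 55 upward and 45 downward (156 with a pseudocount of 0.5, 296 with 0.1 and 361 with limma voom on recovered reads). Against a 1.2-fold threshold 1086 genes passed. The values of the groups did not overlap in 5272 genes (42.2%; chance gives 2.86%). The split between directions rests on the scaling of the libraries: 36% of the changed genes were higher as deposited, 28.5% with equal FPKM totals, 32.8% with equal totals outside the mitochondrial genome, 51.5% after scaling by trimmed means of M values (TMM) and 46.4% after quantile normalisation. The median of all genes moved only between -0.075 and -0.001 over the scalings. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and read counting without stated strand leaves overlapping and antisense genes uncertain.

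**Figure D1:**
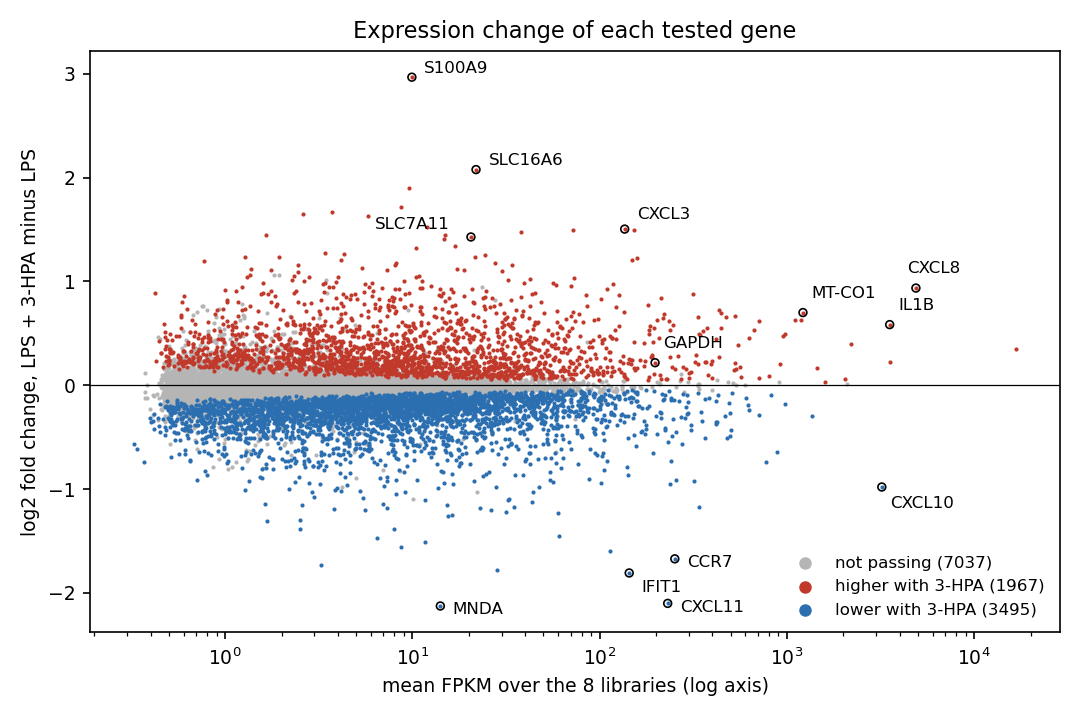
Log2 fold change of each tested gene (vertical axis, LPS + 3-HPA minus LPS) against its mean FPKM over the 8 libraries (horizontal log axis), with 1967 genes higher, 3495 lower and the rest not passing. S100A9 lies highest at 2.97 and MNDA lowest at -2.13.

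Inflammatory cytokine and chemokine genes moved apart rather than together. CXCL8, which encodes the neutrophil attractant IL-8, went from 3350 ± 155.8 to 6406 ± 116.2 FPKM (log2 fold change 0.94, adjusted p = 4.71e-08). IL1B, for the fever-inducing cytokine IL-1β, went from 2828 ± 43.3 to 4239 ± 57.3 FPKM (0.58, adjusted p = 1.8e-08), and PTGS2, for the prostaglandin-producing enzyme COX-2, rose by 0.76. IL6, whose product drives the acute-phase response, fell from 14.1 ± 0.104 to 7.02 ± 0.604 FPKM (-0.92, adjusted p = 8.27e-07). Chosen after their values were seen, IL23A (-0.92), CCL2 (-0.38) and CCL5 (-1.02) fell too. Of the 20 tested members of the cytokine and chemokine list, 11 rose, 7 fell and 2 did not pass, with a median of 0.415. The camera test, which asks whether a list moves against all other genes, gave an adjusted p of 0.00795 for it, but adjusted p = 0.381 with an estimated correlation and 0.0557 under TMM scaling. TNF, the gene of a main early LPS cytokine, held only 8 to 37 reads per library, so it lay below the filter and was not tested.

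NF-κB feedback targets mostly fell: 17 of 25 were lower, among them the costimulatory genes CD80 (-1.16) and CD40 (-0.66) and the signalling adaptor TRAF1 (-0.68), while 7 were higher, among them the cytokine-signalling inhibitor SOCS3 (0.885) and the MAP kinase phosphatase DUSP1 (0.48). The list did not pass (camera adjusted p = 0.165), though it did without the filter on low values (adjusted p = 0.00419) and with voom (adjusted p = 0.0499). Among all genes changed, 3495 of 5462 were lower as well, so falls outnumbered rises in general under the deposited scaling. Of 13 inflammasome and pyroptosis genes, 6 fell, among them CASP1 (the IL-1β-processing protease, -0.75), the ATP receptor P2RX7 (-0.35) and the DNA sensor AIM2 (-0.22). IL1B rose with NINJ1 and MEFV, the last pair chosen after their values were seen, and NLRP3 for the sensor protein did not pass (0.13, adjusted p = 0.117); the list gave an adjusted p of 0.747. Immediate-early genes, which respond first to stimulation, were split with 9 of 19 higher, among them EGR3 (0.99), FOS (0.68) and BTG2 (0.29), and 6 lower (adjusted p = 0.069).

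Interferon-stimulated genes formed the broadest decrease. Of 41 tested, 36 fell, 3 rose and 2 did not pass, with a median of -0.582. The T-cell chemokine gene CXCL10 went from 4258 ± 115.6 to 2158 ± 52.8 FPKM (log2 fold change -0.98, adjusted p = 1.16e-08). The antiviral genes IFIT1 (from 224.1 ± 5.89 to 63.3 ± 3.12 FPKM) and ISG15, a ubiquitin-like modifier (-1.17), fell as well, as did the tryptophan-degrading enzyme gene IDO1 (-0.265). Among the exceptions were CXCL9 (0.22) and the transcription factor gene IRF1 (0.10), chosen after their values were seen. The list gave a camera adjusted p of 1.7e-15 (adjusted p = 0.213 with an estimated correlation), and 34 to 36 members fell under each scaling tried.

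**Figure D2:**
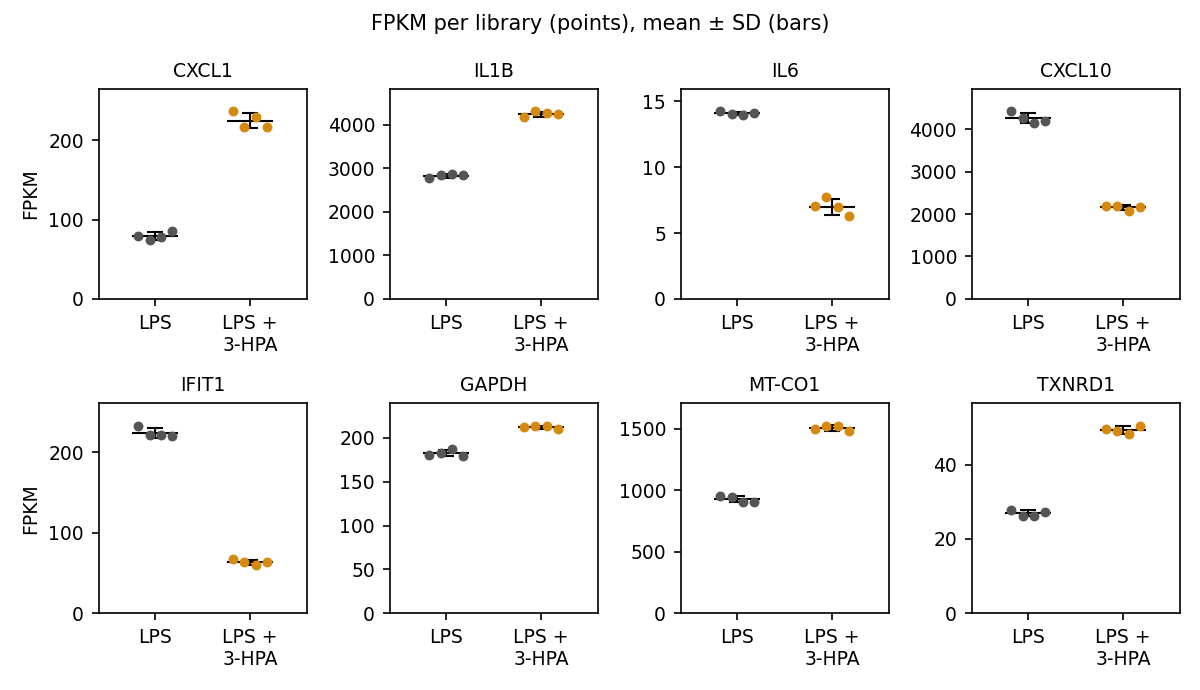
FPKM in each library (points, vertical axis) of 8 genes with LPS or LPS + 3-HPA, with mean ± SD (bars, n = 4). CXCL1, IL1B, GAPDH, MT-CO1 and TXNRD1 lay higher with 3-HPA in every library than in any LPS library, and IL6, CXCL10 and IFIT1 lower.

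Glycolysis genes went both ways and the list as a whole did not pass. GAPDH (ENSG00000111640; chromosome 12, 6533927 to 6538374), for the enzyme whose modification the series title names, rose from 182.6 ± 3.53 to 212.3 ± 1.66 FPKM (log2 fold change 0.22, SE 0.016, adjusted p = 6.75e-06). PFKFB3 (0.585) and PFKFB4 (0.70), which make an activator of phosphofructokinase, and the lactate exporter SLC16A3 (0.27) rose, whereas the phosphoglycerate mutase gene PGAM1 fell by 0.41 and the hexokinase gene HK2 by 0.10. The pyruvate kinase gene PKM (-0.01, adjusted p = 0.658) and the glucose transporter gene SLC2A1 (0.00, adjusted p = 0.995) did not pass, though PKM passed upward under TMM scaling (0.05, adjusted p = 0.0365) and downward with equal totals (-0.05, adjusted p = 0.0406). Of 19 glycolysis genes, 7 rose and 5 fell (7 and 6 adjusted over the list alone), with a camera adjusted p of 0.29; TMM scaling gave 9 and 2 and equal totals 7 and 7. The remaining decreases, chosen after their values were seen, were in ENO1, PFKL and SLC2A3. The HK2 and PFKL calls ended under TMM (adjusted p = 0.0775 and 0.132), and that of SLC2A3 without LPS library 2 or 4 or 3-HPA library 1 or 4 (adjusted p 0.0531 to 0.0709) and under TMM and quantile scaling. LDHA, for lactate dehydrogenase, held 0 to 16 reads per library and was not tested.

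Pentose phosphate genes, which supply NADPH, mostly rose, among them PGD (0.71), TALDO1 (0.66) and TKT (0.53). RPE and RPIA, chosen after their values were seen, fell, though the RPIA call ended with the replicate number as a block (limma adjusted p = 0.0517). The 4 increases among 7 tested genes gave a median of 0.529 and a camera adjusted p of 0.0265, but adjusted p = 0.213 with an estimated correlation and 0.06 under TMM scaling. Of 18 hypoxia targets, 3 rose, namely the stress gene NDRG1 (0.735), the mitophagy receptor BNIP3L (0.28) and ZNF395, named after its value was seen. A further 6 fell, among them VEGFA for an angiogenic factor (-0.36) and the oxygen-regulated transcription factor gene HIF1A (-0.29), and PDK1 did not pass (0.00, adjusted p = 0.968). The hypoxia list gave an adjusted p of 0.819. PDK4, for another kinase of pyruvate dehydrogenase, had at most 4 reads in a library.

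Every one of the 13 protein-coding transcripts of the mitochondrial genome rose, under each scaling tried. MT-CO1 (chromosome M, 5904 to 7445), for a cytochrome oxidase subunit, went from 927.1 ± 24.8 to 1506 ± 21.99 FPKM (log2 fold change 0.70, SE 0.021, adjusted p = 2.52e-08), MT-CYB rose by 0.70, MT-CO3 by 0.67 and MT-ND4L by 0.62. The median was 0.653, with a camera adjusted p of 1.58e-13 (adjusted p = 0.213 with an estimated correlation). The mitochondrial ribosomal RNAs MT-RNR1 (0.53) and MT-RNR2 (0.50), chosen after their values were seen, rose too. The mitochondrial genome took 2.94 to 3.08% of the FPKM with LPS and 4.37 to 4.58% with 3-HPA.

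The nuclear genes for the respiratory chain did not share this rise. Of 29 tested complex I genes 27 did not pass; NDUFS8 rose (0.36) and NDUFAB1 fell by 0.15, the latter ending without LPS library 2 or 3 or 3-HPA library 3 or 4 (adjusted p 0.0901 to 0.104) and under TMM and quantile scaling. Adjusted over the list alone, 1 rose and 0 fell. Of 37 genes of complexes II to V, UQCRC1 rose (0.48), 8 fell, among them the electron carrier gene CYCS (-0.28) and COX7C (-0.21), and 28 did not pass (1 and 7 adjusted over the list alone). These splits turned with the scaling: TMM gave 6 higher and 0 lower for complex I and 6 and 2 for complexes II to V, and equal totals gave 1 and 6, and 1 and 14. Neither list passed (adjusted p = 0.772 and 0.943).

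Among 26 genes of the TCA cycle and pyruvate dehydrogenase, 4 rose and 7 fell. IDH2, for an NADPH-forming isocitrate dehydrogenase, rose by 0.42 and the phosphatase gene PDP1 by 0.28, while the citrate synthase gene CS fell by 0.28 and the pyruvate carrier gene MPC1 by 0.41 (list adjusted p = 0.943; TMM 4 and 3). PC and IDH3G, chosen after their values were seen, were the other increases, that of IDH3G ending without LPS library 1, 3 or 4 or 3-HPA library 1, 2 or 4 (adjusted p 0.0535 to 0.082) and with equal totals. Of 22 fatty acid oxidation genes 5 rose and 8 fell (adjusted p = 0.747; TMM 6 and 5). The acyl-CoA dehydrogenase gene ACADVL (0.39) and the lipid-droplet gene PLIN2 (0.36) rose with CPT1A, PPARD and ETFDH, these 3 chosen after their values were seen, and ACSL1 (-0.25) and ACAA1 (-0.21) fell. The PPARD call ended with equal totals (adjusted p = 0.0518), and that of ETFDH without LPS library 1, 3 or 4 or 3-HPA library 1, 2 or 4 (adjusted p 0.0541 to 0.0944) and with equal totals. Among 14 genes of mitochondrial biogenesis, the helicase gene TWNK (-0.37), the transcription factor gene TFB2M (-0.30) and the deacetylase gene SIRT1 (-0.23) fell and 0 rose (adjusted p = 0.965).

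Genes for breaking down propionate and 3-HPA itself mostly did not pass, with 10 of 14 not passing. HIBADH (-0.115, adjusted p = 0.332) and HIBCH (-0.07, adjusted p = 0.423), enzymes of valine breakdown through 3-hydroxy acids, did not pass, and the propionyl-CoA carboxylase gene PCCA rose by 0.255. ALDH6A1 (-0.165), MMUT (-0.15) and ECHS1 (-0.15) fell, but none of them under TMM or quantile scaling (1 and 0 by either), and adjusted over the list alone 1 rose and 2 fell (list adjusted p = 0.943). These calls ended without 3-HPA library 1 for ECHS1 (adjusted p = 0.0614), without LPS library 2, 3 or 4 or 3-HPA library 1 or 2 for MMUT (0.0588 to 0.0728), and without any library but 3-HPA library 1 for ALDH6A1 (0.0552 to 0.102). Of 10 itaconate and immunometabolism genes, 4 rose: ACOD1, which makes itaconate (0.24), the hydroxycarboxylic acid receptor genes HCAR2 (0.91) and, chosen after its value was seen, HCAR3 (0.89), and the cystine transporter gene SLC7A11 (1.43). KMO and IDO1 of tryptophan breakdown fell by 0.57 and 0.265 (list adjusted p = 0.29). HCAR2 and HCAR3 are near-identical copies, so their reads are uncertain.

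**Figure D3:**
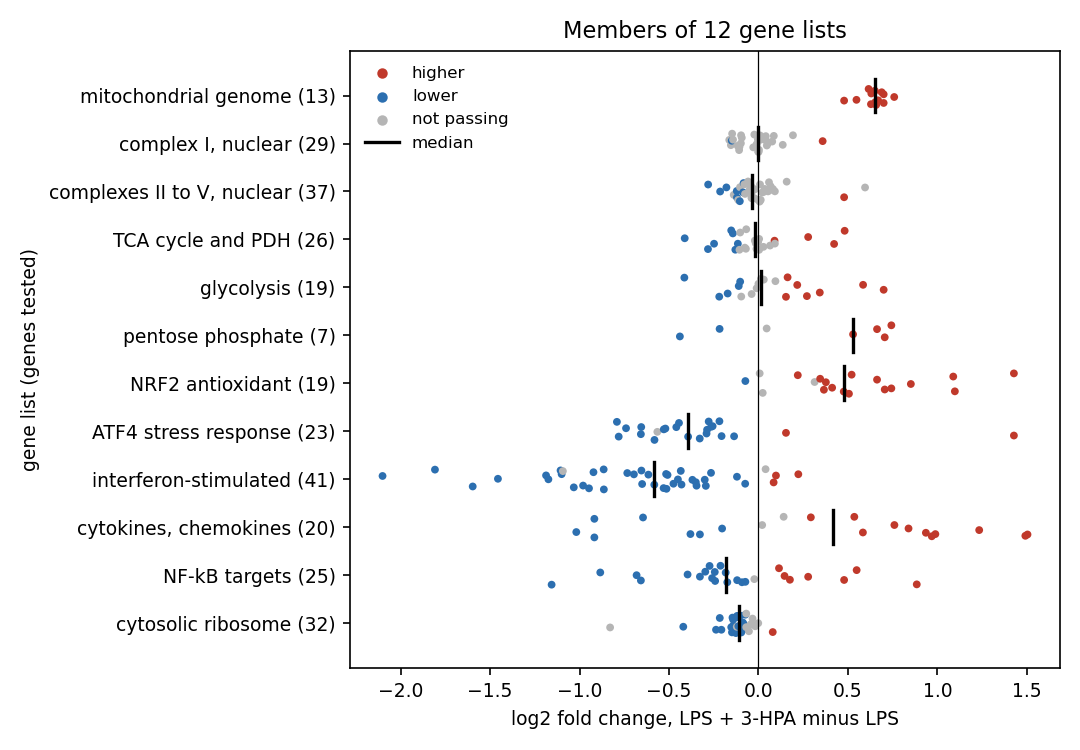
Log2 fold change (horizontal axis, LPS + 3-HPA minus LPS) of each tested member of 12 gene lists, coloured by whether it rose, fell or did not pass, with the median as a line. The 13 transcripts of the mitochondrial genome lie together near a median of 0.653 under the deposited scaling and stayed higher under each other scaling, while medians near 0 for glycolysis, the TCA cycle and the nuclear respiratory genes changed sign with the scaling.

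Targets of the oxidant-sensing factor NRF2 rose. SLC7A11 (1.43), the thioredoxin reductase gene TXNRD1 (0.85; from 26.9 ± 0.810 to 49.4 ± 0.986 FPKM) and, chosen after its value was seen, the haem oxygenase gene HMOX1 (1.098) were among 15 of 19 that were higher, and 3 did not pass. NFE2L2, the gene of NRF2 itself, also chosen after its value was seen, fell by 0.07, a call that ended under TMM (adjusted p = 0.724). The list had a median of 0.477 and a camera adjusted p of 1.31e-10 (adjusted p = 0.0662 with an estimated correlation), and it shares 3 tested members with the pentose phosphate list. Targets of the amino-acid stress factor ATF4 fell, with 20 of 23 lower and a median of -0.393. GDF15, for a stress-induced cytokine, went from 969.1 ± 13.2 to 580.1 ± 16.7 FPKM (-0.74), and DDIT3 for the factor CHOP (-0.79) and the pseudokinase gene TRIB3 (-0.655) fell too. SLC7A11, shared with the NRF2 list, and CEBPB (0.15), chosen after its value was seen, rose, though CEBPB did not pass after quantile normalisation (adjusted p = 0.0529). The ATF4 list gave a camera adjusted p of 3.55e-06 (adjusted p = 0.213 with an estimated correlation).

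Of 16 unfolded-protein-response genes 8 rose, among them the endoplasmic-reticulum chaperone genes HSP90B1 (0.715), PDIA4 (0.54) and CALR (0.20), and 4 fell (adjusted p = 0.069): EDEM1 (-0.29) and, chosen after their values were seen, ATF6, SEL1L and XBP1, of which the last pair did not pass under TMM (adjusted p = 0.463 and 0.64). Of 11 heat-shock genes 7 fell, among them DNAJA1 (-0.26), HSPB1 (-0.25), HSPD1 (-0.23) and HSP90AA1 (-0.20), and 3 rose, namely DNAJB1, HSPA8 and BAG3, chosen after their values were seen (4 and 7 adjusted over the list alone; adjusted p = 0.747; TMM 3 higher and 4 lower). The BAG3 call ended without LPS library 1, 3 or 4 or 3-HPA library 1, 3 or 4 (adjusted p 0.0614 to 0.0895) and with equal totals. Of 14 p53 targets, CDKN1A for a cell-cycle inhibitor (0.455) and SESN1 (0.33) rose with XPC and RRM2B, and BBC3 for a pro-death protein (-0.46) and TNFRSF10B (-0.43) fell with AEN, MDM2 and FAS; XPC, RRM2B, AEN, MDM2 and FAS were chosen after their values were seen (list adjusted p = 0.804). The FAS call ended without the filter on low values (adjusted p = 0.0577). Of the metallothionein list 7 genes were tested, most of them for proteins that bind zinc and copper (list adjusted p = 0.943). MT1G rose (0.34), MT2A fell by 0.35 and MT1E by 0.15. The MT1E call ended without any library but 3-HPA library 3 (adjusted p 0.0567 to 0.101) and under TMM and quantile scaling. Those scalings gave 2 higher and 1 lower.

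Sterol and lipid genes were mixed. The sterol-feedback gene INSIG1 (0.99), the squalene epoxidase gene SQLE (0.62) and MSMO1 (0.29) were among 6 of 19 cholesterol-synthesis genes that rose, and 5 fell, among them the lanosterol synthase gene LSS (-0.62) with SC5D, STARD4 and MVD, these 3 chosen after their values were seen (7 and 5 adjusted over the list alone; list adjusted p = 0.269). Of 11 fatty-acid-synthesis genes, the malic enzyme gene ME1 (0.51) and MID1IP1 (0.25) rose, and the desaturase gene SCD (-0.47) and ACSL3 (-0.44) fell with SREBF1, ELOVL5 and LPIN1, these 3 chosen after their values were seen (2 and 7 adjusted over the list alone; adjusted p = 0.747). The LPIN1 call ended without LPS library 2, 3 or 4 or 3-HPA library 1, 2 or 3 (adjusted p 0.065 to 0.112) and under TMM and quantile scaling. Of 19 LXR and PPAR lipid genes 7 rose, among them LPL (0.34), FABP5 (0.325) and PLIN2, and 3 fell, namely PPARG (-0.39) and, chosen after their values were seen, PLTP and CD36 (7 and 4 adjusted over the list alone; adjusted p = 0.364; equal totals 5 and 6). Of 25 lysosomal genes 9 rose, among them the protease gene CTSL (0.72), and 8 fell, among them GPNMB (-0.88) and the lysosomal regulator TFEB (-0.40) (9 and 9 adjusted over the list alone; adjusted p = 0.804; equal totals 7 and 11).

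Macrophage identity genes were mixed as well. The LPS co-receptor gene CD14 (0.77), the growth-factor receptor gene CSF1R (0.49) and the myeloid transcription factor gene SPI1 (0.225) were among 9 of 16 that rose. The chemokine receptor gene CCR1 (-0.43) fell, together with CD86, FCGR2A, TLR4 and FCGR1A, these 4 chosen after their values were seen (list adjusted p = 0.167). Of 14 genes of alternative activation and resolution, the engulfment receptor gene MERTK (1.40) and the transglutaminase gene TGM2 (1.00) rose, with FABP4, TGFB1 and IL4R chosen after their values were seen. The IL-1 receptor antagonist gene IL1RN (-0.73), PPARG (-0.39) and the scavenger receptor gene CD163 (-0.34) were among 6 that fell (list adjusted p = 0.943). Only 3 genes of MHC class II presentation could be tested, of which the invariant chain gene CD74 fell (-0.52), and 4 of class I, of which B2M rose (0.09) and PSMB10 (-0.10) and NLRC5 (-0.06) fell; both lists were too small for a list test. The PSMB10 call ended without LPS library 1, 2 or 4 or 3-HPA library 1, 2 or 3 (adjusted p 0.0552 to 0.111) and under TMM and quantile scaling. That of NLRC5 ended without any library but 3-HPA library 3 (adjusted p 0.0512 to 0.0936) and after quantile normalisation, and under TMM NLRC5 stood at 0.002. Of 96 protein-coding genes in the MHC region, 84.4% lay under the filter value.

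Ribosome and cell-cycle genes that passed mostly fell, and replication histone genes were split. Of 32 cytosolic ribosome genes 21 fell, among them RPSA (-0.42), RPL32 (-0.24) and RPS19 (-0.22), and RPL23 rose (0.08; chosen after its value was seen; adjusted p = 0.071 with equal totals). The list gave a camera adjusted p of 0.00646, with 1 and 22 adjusted over the list alone, but adjusted p = 0.523 with an estimated correlation and 0.128 under TMM, where 9 fell. Ribosomal genes have many processed copies in the genome, so their reads are uncertain. Of 21 cell-cycle genes 5 fell and 0 rose (0 and 4 adjusted over the list alone; adjusted p = 0.167): TOP2A (-0.455), TPX2 (-0.42), MCM3 (-0.35), MKI67 (-0.25) and, chosen after its value was seen, MCM7, whose call ended without LPS library 2 or 3 or 3-HPA library 1, 3 or 4 (adjusted p 0.0716 to 0.0746) and under TMM and quantile scaling. Of 10 replication histone genes, H2BC21 (0.42) and H2BC8 (0.33) rose and H2BC5 (-0.37) and H2AC6 (-0.30) fell (list adjusted p = 0.828); the H2BC8 call ended without LPS library 2 or 3 or 3-HPA library 1 or 2 (adjusted p 0.0663 to 0.0732).

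Markers of other cell types were sparse, and in libraries of the THP-1 line alone a change in such a gene is not evidence of other cells. Of the T and NK list 4 genes could be tested: the granule gene GNLY rose (0.785), TRAC (-0.37) and IL7R (-0.33) fell, and NKG7 did not pass (-0.05, adjusted p = 0.804). PAX5 was the only tested gene of the B and plasma cell list and fell by 0.89. COL1A1 (0.65) and the adhesion gene PECAM1 (0.86) were the tested genes of the fibroblast and endothelial list and both rose. Of the erythroid and epithelial lists 0 genes could be tested. Of the undifferentiated THP-1 list, MYB fell by 0.345 and CD33 did not pass (-0.02, adjusted p = 0.801).

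Altogether 31 of 39 fixed lists held enough genes for camera, and 7 were called with its preset correlation: the mitochondrial genome, pentose phosphate, cytokine, interferon, NRF2, ATF4 and ribosome lists. With the correlation estimated from the data camera called 0 lists (5 at an unadjusted p under 0.05; lowest adjusted p 0.0662), so none of the 7 held there. The fry test, which asks whether the genes of a list move, on balance, one way and does not compare them with other genes, called 21 lists, glycolysis among them (adjusted p = 0.0195). For lists where no count adjusted over the list alone is given, it equalled the count over all genes. Camera pointed upward while the median lay below 0 for complex I (-0.003), complexes II to V (-0.035), the TCA cycle (-0.017), mitochondrial biogenesis (-0.008), lysosome (-0.016), p53 (-0.024), replication histones (-0.006), the LXR list (median -0.002, mean 0.056) and alternative activation (median -0.085, mean 0.083). The median of all genes was -0.047, lower than each of these medians but that of alternative activation. Median and mean also differed in sign for fatty acid oxidation (0.009 and -0.001), MHC class II (0.043 and -0.134) and the T and NK list (-0.187 and 0.01).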

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

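The tests chosen only after the result was seen were those of scaling, of the nuclear respiratory genes, of a weaker LPS response, of IFNB1, of the MHC region and of the other splits of the libraries, whereas those of GC content and length, of nuclear-retained RNAs and of exon overlap were set out before their results were seen.

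Among 444 groups of 4 libraries checked (217 genes and 5 library measures), 21 held a library standing apart from the others of its group by Dixon's criterion, and chance marks about 1 in 20 groups, or 22.2 here. With LPS alone, library 1 stood apart for IFIT1 (232.9 FPKM against 220.5 to 221.5), IFIT2 (181.2 against 167.9 to 169.4), IL1B (2763 against 2847 to 2854), H2BC5 (21.1 against 19.0 to 19.1) and FABP4 (0.857 against 1.18 to 1.22), and it alone listed PDK4 above 0 (0.0117). Library 2 stood apart for ACADVL (22.5 against 21.9 in the others) and MVD (10.5 against 10.8 to 10.9), library 3 for RPS19 (94.1 against 91.5 to 91.7) and RPL23 (46.1 against 47.2 to 47.3), and library 4 for ENO1 (175.2 against 181.6 to 181.7). With 3-HPA, library 1 stood apart for TRAF1 (81.5 against 77.2 to 77.7), CXCL9 (366.1 against 402.2 to 409.8) and TLR4 (2.73 against 2.48 to 2.52). Library 2 did so for MMP10 (19.4 against 17.6 to 17.9), SEL1L (13.5 against 12.8 to 12.9) and MCM7 (12.9 against 12.1 to 12.2). Library 3 did so for MNDA (3.99 against 4.75 to 4.91), MT-RNR2 (1199 against 1128 to 1136), LSS (1.87 against 1.65 to 1.68) and PDK4 (0.0494 against 0 in the others).

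Of the 35 splits of the 8 libraries into 4 against 4, only the real 1 gave as many changed genes (5462, highest other 1). The same held for genes changed at least 2-fold (100, highest other 1). Relabelling of these libraries thus does not give either count. Each other split mixes the groups, which adds their difference to the spread, so its low count does not estimate the number of false calls. The splits also cannot tell 3-HPA from another difference between the groups, such as a difference between cultures. For the number of lists called, 2 of the 35 splits gave as many (7 in the real split and 7 in the highest other). That other split kept 3 libraries of each group together and so still carried part of the group difference. It is not a reference without change, so it cannot decide whether chance gives 7 lists. The 16 splits that keep 3 libraries of a group together called 4 to 7 lists with at most 1 gene, and the 18 even mixtures called 0 lists. Taken singly, the mitochondrial genome, pentose phosphate, interferon, NRF2 and ATF4 lists had a p as small in 1 split, the real one, the cytokine list in 2 and the ribosome list in 4. The same limit holds for these counts, since the other splits mix the groups.

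Transcripts of the mitochondrial genome were higher with 3-HPA, with a median log2 fold change of 0.653. Removing the trend of fold change on GC content and gene length left the median at 0.676 (range 0.50 to 0.763), which argues against that bias as the whole cause. The lowest median over the scalings was 0.569. The scalings moved the median of all genes only between -0.075 and -0.001, so they could not have removed a rise of this size. They therefore cannot decide whether a fall of most other RNA lies behind it. RNAs kept in the nucleus (4 of 8 listed could be tested) had a median of -0.031 with a range of -0.263 to 0.055. They did not show the rise that loss of cytoplasmic RNA from damaged cells would give. FTX (mean 0.531 FPKM) was too low to show much of such a rise on the log2(FPKM + 1) scale. MALAT1 (2.155) would show it reduced, and it stood at 0.055. That leaves MALAT1, TUG1 (-0.053) and NEAT1 (-0.263), which did not rise but are too few to exclude such a loss. The 66 nuclear-encoded respiratory subunits had a median of -0.021, against a joint rise of the nuclear genes for the chain. A change in the transcription or decay of mitochondrial RNA, in mitochondrial content, or in how the unstated library selection captured these RNAs may each lie behind the pattern and stays untested.

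Interferon-stimulated genes fell while the neutrophil-attracting CXC chemokine genes CXCL1, CXCL3 and CXCL8 rose with 3-HPA. After removal of the trend on GC content and length the interferon list kept a median of -0.542 (range -2.01 to 0.311), against that bias as the whole cause. Outside the CXC genes, 5 of 14 cytokine and chemokine genes rose and 7 fell, and of 25 NF-κB feedback targets 7 rose and 17 fell. Of all genes changed, 3495 of 5462 were lower too. A uniform weakening of the response to LPS would lower the cytokine genes together. The 5 rises, among them IL1B (0.58) and PTGS2 (0.76), argue against it for those genes. A response weaker only in part could not be told apart from other causes, since no library was unstimulated. Less transcript of the interferon beta gene is a candidate explanation that cannot be told apart from others here, since IFNB1 held at most 6 reads in a library. A direct effect of 3-HPA on interferon signalling stays open and untested.

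Genes usually abundant in macrophages lay near 0 reads in every library of both groups, among them TNF (8 to 37 reads), LDHA (0 to 16), HLA-C (6 to 11), CD68 (2 to 11), CCL3 (0 to 3) and CCL4 (0 to 4). In the MHC region of chromosome 6, which holds TNF and HLA-C, 84.4% of 96 protein-coding genes lay under 0.5 FPKM against 38% of 722 on the rest of the chromosome, a difference of 46.4 points, which is consistent with reads shared between alternative copies of that region having been dropped. Where other genes cover most of a gene's exons, 70.6% of 494 genes lay under 0.5 FPKM against 35.9% of 11302 with almost no overlap, a difference of 34.7 points, which is consistent with reads lost where exons overlap and may apply to CD68 (85.8% covered) and CCL3 (74.6%). LDHA and CCL4 lie outside the MHC region with 0% overlap, so neither comparison covers them and their low values stay open. Whether reads shared between copies of genes outside the MHC region were dropped was not tested. The design gives no biological explanation for these low values and none was tested.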

How the results depend on the processing

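The tests chosen only after the result was seen were limma voom on the recovered reads and equal FPKM totals outside the mitochondrial genome; the other alternatives were planned.

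Of the 5462 genes called, 0 were called in the opposite direction under any of the 20 alternatives, 4437 to 5453 were called with the same sign, and 99 or 100 of the 100 genes changed at least 2-fold were shared. Genes changed numbered 4825 to 5926 over the alternatives other than treat, which gave 1086 because it asks for more than a 1.2-fold change. Leaving out each library in turn gave 4931 to 5050 genes changed, 99 to 106 genes at least 2-fold, 7 to 9 lists called, adjusted p of 0.212 to 0.347 for glycolysis and 8.97e-14 to 5.84e-13 for the mitochondrial genome list, and 0.21 to 0.23 for the log2 fold change of GAPDH.

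The number of genes changed at least 2-fold was 296 with a pseudocount of 0.1, 156 with 0.5 and 361 with voom, all of which shrink low genes less by construction. The number of lists called was 12 without a filter, 4 under TMM, 0 with an estimated correlation and 21 by fry; the cause was not tested. Without a filter the NF-κB (adjusted p = 0.00419), unfolded-protein (0.0367), cell-cycle (0.00627) and immediate-early (0.0367) lists passed, as did the fibroblast and endothelial list (0.0143), which was too small for a list test with the filter, and under TMM the pentose phosphate (0.06), cytokine (0.0557) and ribosome (0.128) lists no longer did. With an estimated correlation the cytokine list gave 0.381 and the mitochondrial genome list 0.213, and fry gave 0.0195 for glycolysis. The unfolded-protein list also passed without 3-HPA library 3 or 4 (adjusted p = 0.0432 and 0.0399) and the immediate-early list without 3-HPA library 3 (0.0386), and the NF-κB list with voom (0.0499).

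Of 228 genes tested by name or rule, 213 were called, 25 of these lost the call under at least 1 alternative, 6 others gained it, and 2 changed direction under TMM. Those were NLRC5, at 0.002 (adjusted p = 0.939), and PKM, at 0.054 (adjusted p = 0.0365); TMM raises the median of all genes from -0.047 to -0.001, which moves both upward. NLRP3, which did not pass, passed upward under TMM (0.179, adjusted p = 0.0472) and without LPS library 2 (0.175, adjusted p = 0.0484).

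With a replicate block 5074 genes changed, 4854 of them shared with the fit without it. Deviations of same-numbered libraries correlated at -0.023, -0.003, 0.036 and 0.089, and 2 of 8 libraries correlated best with their own number. By the rule set beforehand, which asked for all 4 correlations above 0.1, the numbers were not taken to pair the libraries. On the second principal component (9.4% of the variance), however, both number-4 libraries lay apart, at -8.16 with LPS and -13.02 with 3-HPA. The others lay at -0.71 to 6.23, so a factor shared by the number-4 libraries cannot be excluded. The change of unit set out before the data were examined, from counts to FPKM or CPM, applied only to a table of counts and was not run. Genes near 0 reads, such as TNF and LDHA, lay below the filter and were not tested.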

Other observations

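All tests in this part were chosen only after the result was seen.

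Nuclear protein-coding genes that share a symbol stem were taken as families, and camera was run on the 249 families with at least 6 tested genes. Symbols with more than 1 letter after the first number were left out, since they can stand for opposite-strand or binding-protein genes. A wider run on 262 families kept them and the mitochondrial genome. Of the 249 families 6 were called. The wider run called 12, adding the mitochondrial genome and the stems SH, ATF, TNFSF, GBP and CXCL. Matrix metalloproteinase genes, which encode enzymes that cut extracellular matrix, rose in 9 of 13 cases, among them MMP3 (1.28), MMP12 (1.16) and MMP8 (1.03), and only MMP13 fell (-0.66); the adjusted p was 0.000117, or 0.408 with an estimated correlation. Integrin beta genes, for adhesion receptors, rose in 5 of 6 cases, among them ITGB5 (0.69) and ITGB7 (0.61), with 0 lower (adjusted p = 0.00139, or 0.408 with an estimated correlation). Collagen genes rose in 7 of 10 cases, among them COL6A1 (0.98) and COL6A2 (0.63), and 2 fell (adjusted p = 0.0199, or 0.812 with an estimated correlation). The other families called were myosin genes, with 8 of 12 higher and 1 lower (adjusted p = 0.00129, or 0.408 with an estimated correlation), genes with the stem LRP, with 4 of 6 higher and 0 lower (0.0288, or 0.752), and large-subunit ribosomal protein genes, with 32 of 47 lower and 1 higher (0.0199, or 0.832). TNF superfamily ligand genes fell in 4 of 6 cases, among them TNFSF13B (-1.125) for the B-cell factor BAFF and TNFSF10 (-0.79) for the death ligand TRAIL, and 0 rose, but the family did not pass (adjusted p = 0.0574; 0.0451 in the wider run, or 0.763 there with an estimated correlation). Guanylate-binding protein genes fell in 6 of 6 cases, and the family did not pass either (adjusted p = 0.0582; 0.0459 in the wider run, or 0.763 there with an estimated correlation). Under each other scaling of the FPKM values more members of these families moved in the direction given here than in the other, with 4 guanylate-binding protein genes and 14 large-subunit ribosomal protein genes lower under TMM.

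S100A8, the partner subunit of S100A9, went from 0.0701 ± 0.0827 to 1.48 ± 0.397 FPKM, with a log2 fold change of 1.201 on the log2(FPKM + 1) scale (limma adjusted p = 3.97e-05). The 10 most abundant genes took 15.4 to 15.6% of the FPKM with LPS and 18.0 to 18.6% with 3-HPA.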
